A study of Mus musculus with 4 samples.

How the data were processed

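Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in RAW264.7 cells, a mouse macrophage-like line. Per the labels, each well of a 12-well plate received 1000000 cells, which were kept for 48 h after treatment. Of the 4 libraries, 2 carry the label Gel and 2 the label CuNZ@Gel. The groups were taken from the sample titles. The treatment text, the same for every sample, says that cells were treated with CuNZ@Gel, so the records conflict on what the Gel cells received. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

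Per the submitters' processing notes, fastp 0.23.1, Bowtie2 2.3.4.3, SAMtools 1.17, Picard 2.27.5, MACS2 2.2.8 and genome build GRCm39 were used; the role and order of the tools are not given in the sources used here. For each library the authors deposited log2 values for 80929 regions, each named by its nearest gene. These deposited log2 values were read as log2(RPM + 1), with RPM the reads in a region scaled to 1000000 effective reads (reads in regions times a scaling factor per library), because after reversing the logarithm 100% of the low values in each library fell within 0.1 of a whole number of reads. The totals of the reversed values implied these scaling factors, 0.910 and 0.902 for Gel and 1.11 and 1.10 for CuNZ@Gel, whose product was 1.0000. Reads in regions recovered in this way were 18843559 and 17914776 for Gel replicates 1 and 2, and 7440950 and 10236695 for CuNZ@Gel replicates 1 and 2. Total sequenced reads are not given in the sources used here.

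The authors also deposited a peak list per library, called on each library alone, with a fold enrichment (a ratio over background), the -log10 of a p-value and of a q-value, and an integer score derived from the q-value for each peak. These deposited folds and q-values are the authors' own and were used only to rank, filter or describe peaks within a list. The lowest -log10 q listed was 1.303. Merging the 4 lists with a gap of at most 1 base gave 80929 regions, the same number and order as the value tables, and this match gave each region its GRCm39 coordinates, printed here counted from 1. Of 77346 regions whose gene has a chromosome in the RefSeq gene table for GRCm38.p6, 77341 lay on that chromosome; no coordinates from that table were used. Of 26614 gene names, 25207 matched that table. A group of 48 regions on unplaced scaffolds had no coordinates, and 4 rows without a gene name were left out of tests.

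Regions were tested with limma 3.58.1 (R 4.3.3, intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on the deposited log2 values, after keeping regions with at least 10 reads at the median number of reads in regions (0.710 per 1000000 reads in regions) in at least 2 libraries and at least 15 reads in all. The gene value was log2(sum of RPM over the regions nearest to the gene + 1). Such a sum can hide regions that change in opposite directions. Changes are CuNZ@Gel minus Gel on this scale, which understates changes of low values. Filtering left 77014 regions and 25900 genes. The tests planned for counts were replaced by this limma test because the deposited values are on a log2 scale. "Nearest gene" is the authors' assignment and does not place a region in a promoter, exon or intron; positions relative to gene structure were not analysed here because no GRCm39 annotation was used.

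A set of 26 gene lists was fixed before the data were examined and tested with limma's camera (preset correlation 0.01), with a correlation estimated per list, and with fry. With 4 libraries the test with an estimated correlation has few degrees of freedom, so a lack of calls by it decides little. Each list's median change was also placed among 10000 random lists matched on mean level. Genes named in the text follow a rule fixed beforehand: 10 macrophage, inflammatory, oxidative stress and metal response genes reported in any case, the 10 largest rises and 10 largest falls among called genes with a gene symbol (no predicted-gene, Rik or accession names) whose groups do not overlap and whose mean log2 value is at or above the median of tested genes (4.41), 3 genes for each called list, and the 3 group-restricted peak regions per group with the highest smaller fold enrichment. Of the genes this rule selects, 2 are not reported here. Genes named outside it are said to have been chosen after their values were seen. Peak sets were compared with bedtools 2.31.1, and group means of peak counts with an exact two-sided permutation test (scipy 1.17.1), whose smallest p for 2 against 2 libraries is 0.333.

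Alternatives covered scaling (median-of-ratios factors, library totals, cyclic loess, which removes the trend of change with level, and scaling to the genome background pileup recovered from the deposited MACS2 folds), filters, voom, the replicate number as a block, autosomal genes only, pseudocounts 0.25 and 4, region width, equal read numbers, the strongest region per gene, stricter peaks and each library left out. Library totals here are totals of reads in regions, without the scaling factors, and not all sequenced reads. Pseudocounts, background scaling, width, thinning, the strongest region and regions as units of the list test were added after seeing the data. The limma path was tested on simulated counts drawn with the real means and depths and the measured within-group dispersion (0.00926 for regions, 0.00608 for genes). Among 77014 simulated regions, 14.9% of those changed 1.5-fold, 64.2% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, with 0 calls among 76814 unchanged regions. Among 25900 simulated genes the shares were 44.8%, 94.0% and 100%, with 4 calls among 25700 unchanged genes. A simulated list raised 1.5-fold was called, and 0 of the 25 unchanged lists were. The simulated counts held no trend with level, no group difference beyond the planted changes and no correlation between genes. They therefore do not measure false calls that come from scaling, a level trend or correlated genes. Only 66 or 67 features were changed per fold, against 33169 regions called in the real data, so the adjusted threshold was stricter. All regions, and all genes, shared the same dispersion, taken from features with many reads. The recovered shares therefore do not give the power of the real test.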

Results

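Accessibility was profiled in RAW264.7 macrophage-like cells after 48 h in libraries titled Gel (2) or CuNZ@Gel (2), the latter described in the series title as a nanozyme hydrogel. The treatment text is the same for all samples and names only CuNZ@Gel, so what the Gel cells received rests on the sample titles. The comparison asks how chromatin accessibility differed between these groups. The Gel libraries held 18843559 and 17914776 reads in regions and the CuNZ@Gel libraries 7440950 and 10236695. The genome background pileup recovered from the peak lists was 1.003 and 0.962 in Gel against 1.168 and 1.201 in CuNZ@Gel. MACS2 sets this value from all reads it used, peaks included, so it is not a count of background reads. In 1e6 reads, region reads per background pileup were 18.8 and 18.6 in Gel against 6.37 and 8.53 in CuNZ@Gel. Every comparison between the groups coincides with this difference. Total sequenced reads are not given. On the deposited log2 scale, Pearson's r across regions was 0.985 between the Gel libraries, 0.967 between the CuNZ@Gel libraries and 0.914 to 0.916 between groups; regions are not independent replicates.

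Among genes at or above the median level, those whose nearby chromatin fell most in CuNZ@Gel included Acot2, Btg2, Id3 and Zfp36l1. Reads near Btg2, in RPM (reads scaled to 1000000 effective reads, the reads in regions times a scaling factor recovered from the deposited values), fell from 218 ± 2.15 to 83.9 ± 4.28 RPM (mean ± SD, n = 2 per group). Chromatin near Arg1, which encodes arginase, and Il7r, which encodes a cytokine receptor subunit, rose. Among 25900 genes tested, limma called 5319 higher and 9358 lower in CuNZ@Gel, and among 77014 regions 16314 higher and 16855 lower. In 76.9% of genes the groups did not overlap, against 33.3% by chance.

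The split between higher and lower depended on scaling. Removing the trend with level gave 5356 genes higher and 3999 lower, and 14457 regions higher and 10612 lower. Totals of reads in regions alone, without the scaling factors, gave 8888 genes higher and 4840 lower, and 23142 regions higher and 9155 lower. Scaling to the genome background pileup gave 719 genes higher and 19552 lower, and 3740 regions higher and 46697 lower. The median gene change moved from -0.10 to -1.06. Because MACS2 sets that pileup from all reads it used, this background scale does not rest on reads outside peaks alone. A stricter filter gave 1715 genes higher and 8305 lower, and 7498 regions higher and 15718 lower. Directions given here are therefore relative to the deposited scaling.

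Strong regions fell and weak regions rose. In the strongest decile of mean level the median log2 change was -0.60 and 86.9% of regions were called lower, while in the weakest decile the median was 0.35 and 28.1% were called higher. Of the 33169 regions called, 20519 were called in the same direction after this trend was removed.

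**Figure D1:**
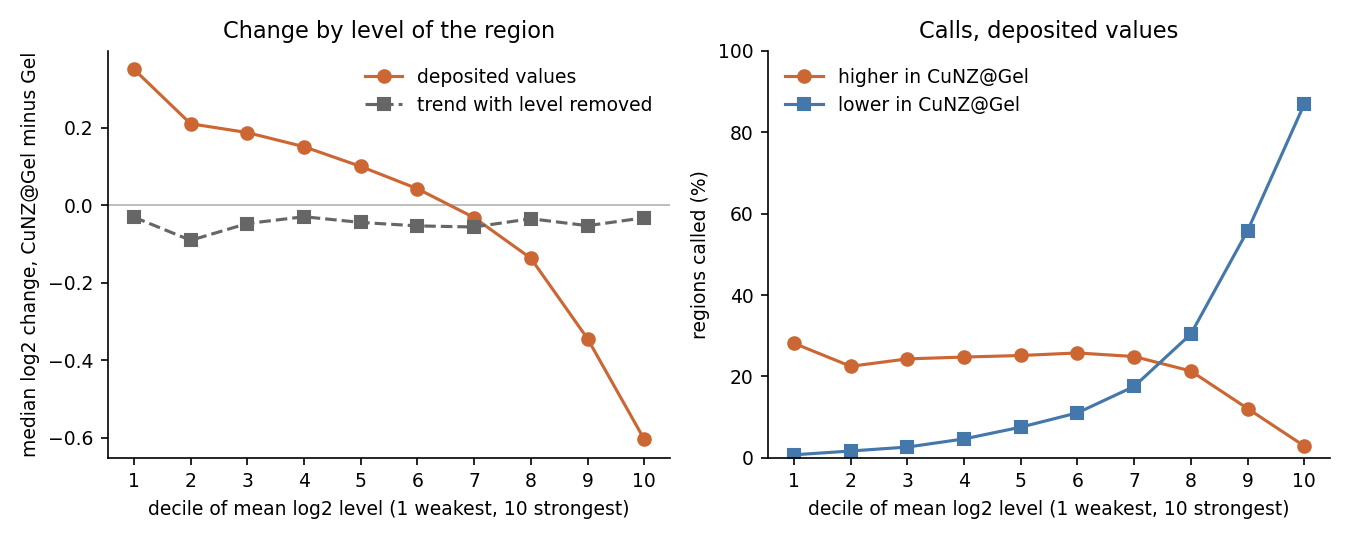
Left, median log2 change (CuNZ@Gel minus Gel) of regions in each decile of mean log2 level, for deposited values and after removal of the trend with level. Right, percent of regions per decile called higher or lower with deposited values: calls of lower regions rise to 86.9% in the strongest decile.

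Among the genes fixed for reporting, Il6 and Tnf, which encode inflammatory cytokines, fell by 0.85 ± 0.10 and 0.79 ± 0.05 (log2 change ± SE; limma adjusted p = 9.68e-07 and 3.64e-10), and Il1b fell by 0.37 ± 0.07 (adjusted p = 7.69e-05). With the trend removed Il6 fell by 0.83 (adjusted p = 6.61e-07), whereas Tnf was at 0.09 (adjusted p = 0.169) and Il1b at -0.10 (adjusted p = 0.242). Arg1 rose by 0.95 ± 0.15 (adjusted p = 2.65e-05), from 9.15 ± 1.66 to 18.5 ± 0.196 RPM. Il10, an anti-inflammatory cytokine gene, rose by 0.31 ± 0.07 (adjusted p = 0.000573) and Mrc1, which encodes the mannose receptor, by 0.53 ± 0.19 (adjusted p = 0.0229). Mrc1 lost its call with the trend removed (0.27), without Gel replicate 1 (0.34) and without CuNZ@Gel replicate 1 (0.25). On the background scale Arg1 was at -0.03, Mrc1 at -0.44 and Il10 at -0.73. Nfe2l2, which encodes the antioxidant regulator NRF2, fell by 0.83 ± 0.05 and the metallothionein gene Mt1 by 0.81 ± 0.06; with the trend removed Nfe2l2 was at -0.17 (adjusted p = 0.00400) and Mt1 at -0.07 (adjusted p = 0.404). Nos2 and Hmox1 showed 0.00 ± 0.09 and 0.00 ± 0.06 (adjusted p = 0.990 and 0.999), although Hmox1 rose by 0.22 with the trend removed (adjusted p = 0.00470), and both were lower on the background scale. These sums hide opposite changes. Of 8 regions near Nos2, 2 were called higher and 1 lower, and of 9 near Hmox1, 3 were called higher and 1 lower.

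Among called, symbol-bearing genes at or above the median level of tested genes (mean log2 value 4.41), the largest rises were those of Rgs8 (1.57 ± 0.12), Tmem26 (1.52 ± 0.08), Pfdn1, Tmem163 (1.47 ± 0.10), Mir3066 (1.45 ± 0.12), Atp4b (1.38 ± 0.12), Naip1 (1.38 ± 0.11), Slc1a2 (1.36 ± 0.11), Il7r (1.33 ± 0.12) and Dlgap2 (1.33 ± 0.09). Some genes of lower level rose more. All 10 were also called higher with the trend removed. On the background scale Rgs8 alone among them passed the test, and the others lay between 0.30 and 0.48. Reads near Pfdn1 rose from 18.5 ± 0.667 to 54.2 ± 0.210 RPM (n = 2), and its most changed region lay on chromosome 18 from 36537709 to 36539041 and rose by 2.37 ± 0.16. The largest falls under the same limit included those of Acot2 (-1.49 ± 0.09), Mir6938 (-1.44 ± 0.08), Mrps6 (-1.39 ± 0.08), Calm2 (-1.38 ± 0.11), Btg2 (-1.37 ± 0.06), Agap1 (-1.35 ± 0.10), Id3 (-1.34 ± 0.07), Zfp36l1 (-1.31 ± 0.07) and Trib3 (-1.31 ± 0.09). All of these genes stayed called lower with the trend removed, at -0.53 (Btg2) to -1.27 (Mir6938).

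Genes for signal-induced transcription factors, which respond early to stimulation, were lower in 28 of 34 cases and higher in 1 (median -0.79; camera adjusted p = 1.52e-10, and adjusted p = 0.212 with an estimated correlation). Fos fell by 1.07 ± 0.03, with all 8 of its regions lower, Ier2 by 1.16 ± 0.04 and Atf3 by 0.96 ± 0.04. The called exception, named after its value was seen, was Fosl1, which rose by 1.175 ± 0.115. Removing the trend left Fos at -0.50, Ier2 at -0.47 and Atf3 at -0.29, and 20 genes lower and 2 higher (adjusted p = 1.89e-06, and adjusted p = 0.649 with an estimated correlation).

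Genes of the unfolded protein and integrated stress response were lower in 21 of 22 cases (median -0.63; camera adjusted p = 2.46e-08, and adjusted p = 0.212 with an estimated correlation). Ddit3 fell by 1.14 ± 0.05 and the chaperone gene Hspa5 by 1.05 ± 0.06. With the trend removed Ddit3 was at -0.19 and Hspa5 at -0.35, and 10 genes were lower and 1 higher (adjusted p = 0.00909, and adjusted p = 0.756 with an estimated correlation). Chromatin remodeller genes were lower in 17 of 24 cases (median -0.52; adjusted p = 0.000302, and adjusted p = 0.234 with an estimated correlation). Arid1a fell by 0.97 ± 0.05, Chd3 by 0.93 ± 0.08 and Hmgb2 by 0.74 ± 0.07; with the trend removed the list had adjusted p = 0.0458 (adjusted p = 0.753 with an estimated correlation) and Arid1a was at -0.46, Chd3 at -0.44 and Hmgb2 at -0.02. These 3 lists were the only calls of the 26 with the trend removed, and none was called there with an estimated correlation.

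The housekeeping control list was lower in 17 of 17 genes (median -0.74; adjusted p = 3.49e-08, and adjusted p = 0.212 with an estimated correlation). Actb fell by 0.78 ± 0.04 and Polr2a by 0.83 ± 0.06, which with the trend removed became -0.13 and -0.09. This control moved with the gene lists called lower, and with the trend removed it lost its call (adjusted p = 0.0977). The 9 other lists called lower lost their calls with the trend removed. So did single genes named here and in the next paragraph, among them Polr2a, Hspa8, Dnajb1, Atp5pb, Irak2, Cebpa and Prmt5. In heat shock genes 10 of 14 were lower (adjusted p = 0.00379, and adjusted p = 0.219 with an estimated correlation), with Hspa8 at -0.95, Dnaja1 at -1.17 and Dnajb1 at -0.72. In hypoxia and glycolysis genes 19 of 25 were lower (adjusted p = 9.53e-05, and adjusted p = 0.212 with an estimated correlation); Mxi1 fell by 0.79, Vegfa by 0.83 and Pkm by 0.60, and Pkm turned to 0.20 with the trend removed. In oxidative phosphorylation genes 17 of 21 were lower (adjusted p = 0.00496, and adjusted p = 0.219 with an estimated correlation), among them Atp5pb (-0.75), Nrf1 (-0.72) and Cox5a (-0.72). Of the genes in these lists that stayed lower with the trend removed, Dnaja1 was at -0.46, Mxi1 at -0.35, Vegfa at -0.38, Cox5a at -0.26 and Nrf1 at -0.71. With deposited values 3 regions near Vegfa were called lower and 2 higher, and of 3 near Polr2a 1 was called lower and 1 higher.

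In pattern recognition and inflammasome genes 23 of 33 were lower (adjusted p = 0.00252, and adjusted p = 0.258 with an estimated correlation), with Nod2 at -0.69, Irak2 at -0.50 and Tlr2 at -0.58. Macrophage identity genes were lower in 16 of 25 cases (adjusted p = 0.00907, and adjusted p = 0.219 with an estimated correlation), with Ptprc at -0.60, Cebpa at -0.71 and Fcer1g at -0.76. The median of this list (-0.30) was not low for its level: 72.7% of level-matched random lists had one as low or lower. Lysosome and phagocytosis genes were lower in 23 of 32 cases (adjusted p = 0.00100, and adjusted p = 0.212 with an estimated correlation), with Ctsl at -1.06, Grn at -0.80 and Abca1 at -0.66. Histone and DNA modifier genes were lower in 32 of 53 cases (adjusted p = 0.00554, and adjusted p = 0.212 with an estimated correlation), with Brd2 at -0.81, Prmt5 at -0.77 and Kdm6b at -0.62, the last turning to 0.27 with the trend removed. Cell cycle genes were lower in 23 of 30 cases (adjusted p = 0.00179, and adjusted p = 0.212 with an estimated correlation), with Cdk4 at -0.89, Ccnd3 at -0.63 and Cdkn1a at -0.82, and cell death and p53 genes in 16 of 25 cases (adjusted p = 0.00121, and adjusted p = 0.212 with an estimated correlation), with Mcl1 at -0.65 and Pmaip1 at -0.67. With the trend removed Cdkn1a was at 0.05 and Mcl1 at 0.04, neither called. The genes of this paragraph that stayed called lower fell by less on that scale: Grn was at -0.13, Brd2 at -0.14 and Cdk4 at -0.16, and the others lay from -0.27 (Nod2) to -0.61 (Ctsl). With deposited values 5 regions near Ptprc were called lower and 2 higher, and near Pmaip1 6 lower and 2 higher. Of 14 regions near Tlr2, 4 were called lower and 4 higher, so its lower sum was not shared by all its regions.

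Fibroblast markers were the only list called higher, with 4 of 10 higher and 0 lower (median 0.24; adjusted p = 0.0339, and adjusted p = 0.258 with an estimated correlation). Col5a1 rose by 0.93 ± 0.15, Col3a1 by 0.99 ± 0.24 and Prrx1 by 0.79 ± 0.23. The list (adjusted p = 0.483) and Prrx1 (0.49, adjusted p = 0.0995) lost their calls with the trend removed. Of level-matched random lists, 77.8% had a median as low or lower. Fibroblast marker levels were low: Col3a1 had 2.21 ± 0.644 RPM in Gel and 5.32 ± 0.146 in CuNZ@Gel. On the background scale Col5a1 and Prrx1 were at -0.04, and Col3a1 at 0.18 lost its call.

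Of the lists without a camera call, classical inflammatory activation genes were lower in 16 and higher in 3 of 33 (adjusted p = 0.0510) and NRF2 antioxidant targets lower in 16 and higher in 5 of 29 (adjusted p = 0.0689). Alternative activation genes were higher in 8 and lower in 7 of 22 (adjusted p = 0.298), interferon response genes higher in 5 and lower in 10 of 31 (adjusted p = 0.672), reactive oxygen species genes higher in 3 and lower in 7 of 18 (adjusted p = 0.706) and metal binding and copper handling genes higher in 4 and lower in 12 of 23 (adjusted p = 0.306). Genes of lipoylation and copper-dependent death were higher in 2 and lower in 7 of 14 (adjusted p = 0.176), wound growth factor and matrix genes higher in 7 and lower in 11 of 33 (adjusted p = 0.549) and osteoclast genes higher in 5 and lower in 4 of 14 (adjusted p = 0.480). Lymphocyte markers were higher in 1 and lower in 6 of 14 (adjusted p = 0.747), dendritic cell and granulocyte markers higher in 4 and lower in 3 of 14 (adjusted p = 0.393), and the genes of unrelated tissues higher in 5 and lower in 3 of 14 (adjusted p = 0.148). Against level-matched random lists, the medians of osteoclast (99.8% as low or lower), alternative activation (99.2%) and wound genes (98.2%) lay above the middle 95%. Those of chromatin remodellers (1.02%) and oxidative phosphorylation (1.73%) lay below it, as did the signal-induced (0%), unfolded protein (0.27%) and housekeeping (0.01%) lists. The other lists called lower lay inside it, from hypoxia and glycolysis (6.24%) to macrophage identity (72.7%). Among them were histone and DNA modifiers (34.3%), pattern recognition (44.5%) and lysosome and phagocytosis (53.3%), so their falls were not unusual for their level. The wound list's median (0.07) was above 0 while its fry test pointed lower (adjusted p = 0.0370).

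Adjusted over the list alone, the counts were the same for 19 lists. The exceptions, adjusted over the list alone, were 22 lower in the unfolded protein and integrated stress response, 5 higher in histone and DNA modifiers, 4 higher and 24 lower in lysosome and phagocytosis, 3 higher and 17 lower in cell death and p53, 8 higher in the wound list, 6 higher in osteoclast genes and 2 lower in dendritic cell and granulocyte markers. No list was called with an estimated correlation, where few degrees of freedom leave little room for a call. The fry test, which does not compare a list with other genes, called 22 of 26.

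**Figure D2:**
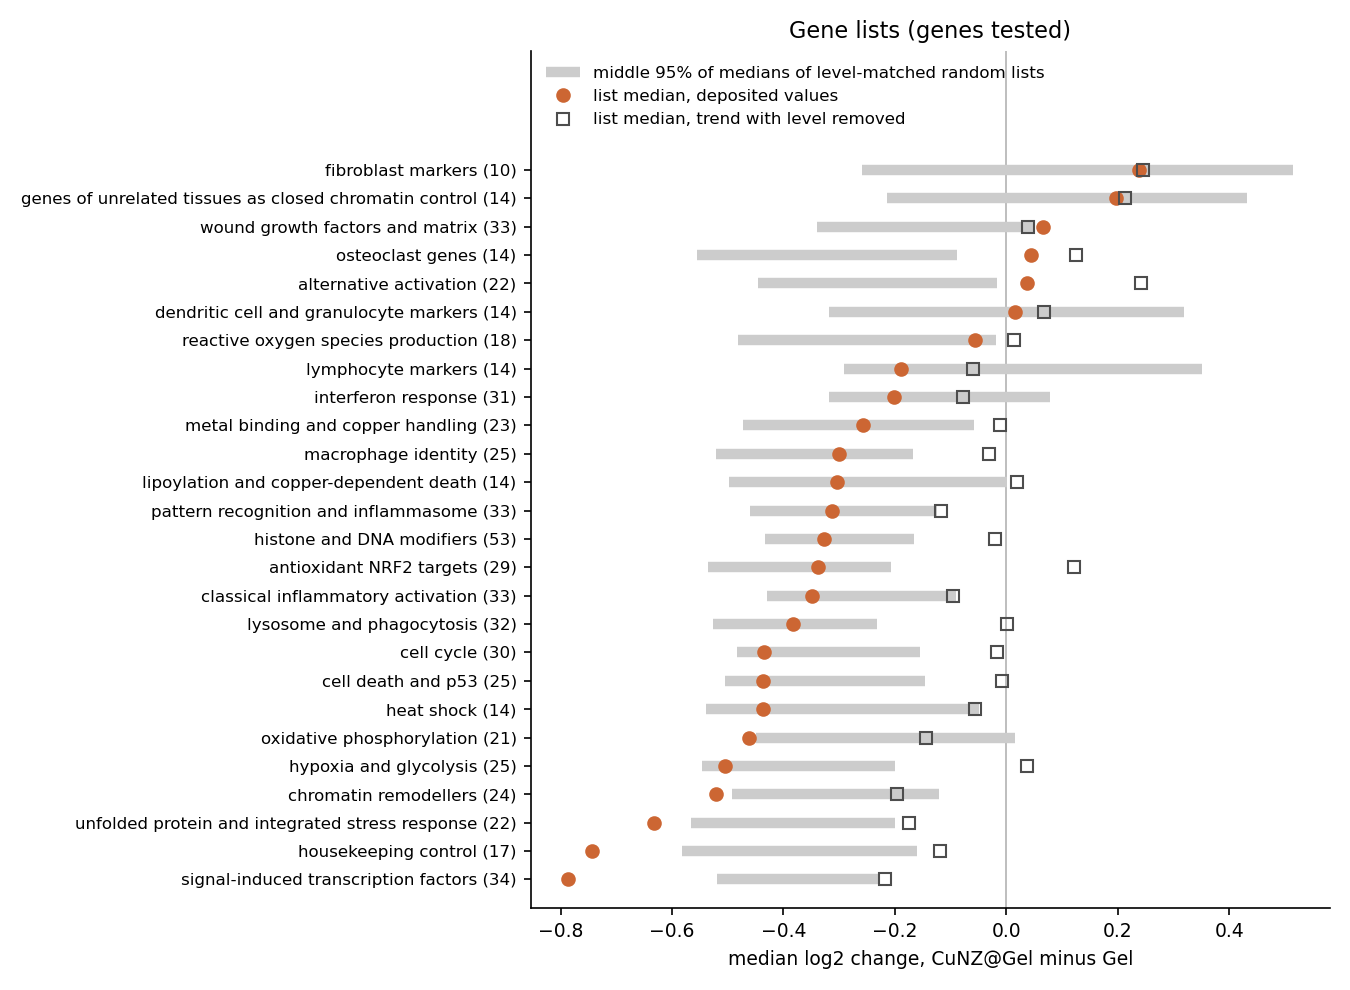
Median log2 change (CuNZ@Gel minus Gel) of each fixed gene list, with the number of genes tested in brackets; filled points are deposited values, open squares have the trend with level removed, and grey bars span the middle 95% of medians of level-matched random lists. Signal-induced transcription factors (-0.79) and the housekeeping control (-0.74) lie lowest.

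Peak lists were shorter in CuNZ@Gel. The Gel libraries had 61757 and 59251 peaks and the CuNZ@Gel libraries 42612 and 53273, a mean of 60504 ± 1772 against 47942 ± 7538 (SD, n = 2; exact permutation p = 0.333, the smallest possible). Median peak width was 481 ± 2.83 bases in Gel and 419 ± 8.49 bases in CuNZ@Gel (exact permutation p = 0.333, n = 2). Both differences coincide with the fewer region reads per background pileup in CuNZ@Gel and cannot be separated from it.

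Of 80929 merged regions, 32082 had a peak in all 4 libraries, 8940 only in both Gel libraries and 1849 only in both CuNZ@Gel libraries. The other ways of pairing the libraries gave 293 to 1440 regions. With the same number of top peaks per library the counts were 4329 and 3482. These counts do not measure loss against gain: the median change was -0.20 in Gel-restricted regions, -0.22 in common ones and 1.51 in CuNZ@Gel-restricted ones. After removal of the trend these medians were -0.39, 0.00 and 1.33. The classes were set by peaks called from the same reads, so a rise in CuNZ@Gel-restricted regions was largely fixed by that choice. Of 1849 such regions, 1739 were called higher and 1 lower. The CuNZ@Gel-restricted regions with the highest fold enrichment lay nearest Colec12 (chromosome 18, 9814403 to 9814854), Gm23517 (chromosome 15, 85308443 to 85308680) and Gm29685 (chromosome 10, 107802927 to 107803567). Reads in the region near Colec12 rose from 4.92 ± 0.0494 to 18.4 ± 1.501 RPM (n = 2, limma adjusted p = 4.67e-12). That region was picked for its peaks in CuNZ@Gel alone, so this p-value is no separate support for a rise. The Gel-restricted regions lay nearest Grp (chromosome 18, 65970358 to 65970539; 8.86 and 7.06 RPM in Gel, 2.42 and 7.64 RPM in CuNZ@Gel, so the groups overlapped), Rps12-ps16 (chromosome X, 125133937 to 125134124; -0.79 ± 0.22) and Mir6415 (chromosome 5, 92624765 to 92625106; -0.42 ± 0.23, limma adjusted p = 0.152).

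**Figure D3:**
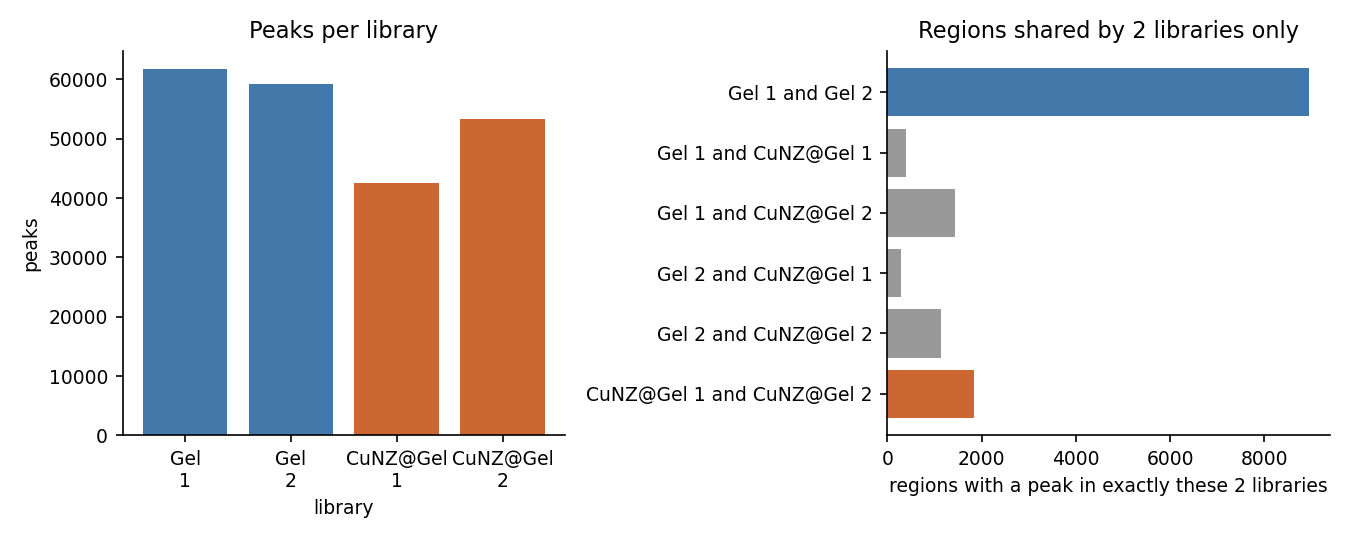
Left, number of peaks listed for each library. Right, number of merged regions with a peak in exactly the 2 libraries named: 8940 for both Gel libraries and 1849 for both CuNZ@Gel libraries.

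X-linked regions were lower in CuNZ@Gel. Of 1379 regions on the X chromosome 421 were called lower and 163 higher, with a median change of -0.24 (limma). With the trend removed the median was -0.32, and 425 were called lower and 116 higher, while autosomal regions had a median of -0.04. Both CuNZ@Gel libraries lay below the Gel mean on X, by medians of -0.30 and -0.28.

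**Figure D4:**
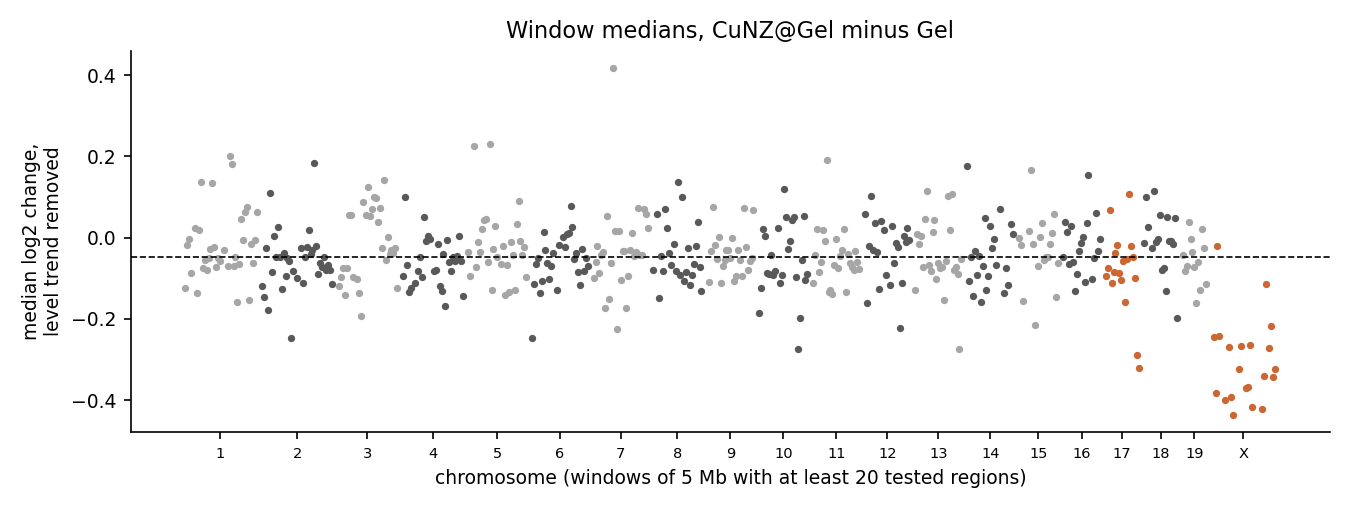
Median log2 change (CuNZ@Gel minus Gel, trend with level removed) of 5 Mb windows with at least 20 tested regions along each chromosome, with chromosomes 17 and X in orange and the autosomal median dashed. Of 21 windows on X, 20 lie below the autosomal median.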

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

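The higher region and gene counts, and the lower ones, stayed within 1.5 times of the main counts with median-of-ratios factors, voom, no filter, other pseudocounts and autosomal genes only. Library totals of reads in regions gave 9155 regions lower, and 8888 genes higher with 4840 lower. Cyclic loess gave 10612 regions and 3999 genes lower. The stricter filter tests fewer features and gave 7498 regions and 1715 genes higher. Background scaling, which shifts the median gene change to -1.06, gave 3740 regions higher and 46697 lower, and 719 genes higher and 19552 lower. Leaving out each library gave 11530 to 14953 regions higher and 12098 to 16608 lower, 4038 to 5018 genes higher and 7758 to 8985 lower; the lone library of a group is assumed to vary like the others. The lists called, 14 in the main test, numbered 9 with library totals, 3 with cyclic loess, 5 with the stricter filter, 9 with the width trend removed, 0 with an estimated correlation, 22 by fry and 7 with regions as units, and 14 to 16 without each library.

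The peak ratio (CuNZ@Gel over Gel, 0.792) ranged from 0.704 to 0.880 without each library. The width ratio moved from 0.871 to 0.761 with the same number of top peaks, where CuNZ@Gel-restricted regions numbered 3482 and Gel-restricted ones 4329. Leaving out a library needs fewer libraries to agree and gave 2550 to 8322 CuNZ@Gel-restricted, 10631 to 16928 Gel-restricted and 32783 to 39445 common regions.

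Of 1219 named-gene results under alternatives, 1173 kept their side of the threshold and, where called in the main test or the alternative, their direction; 14 such results changed direction. With cyclic loess these were Tnf (0.0935), Hmox1 (0.22), Pkm (0.20), Kdm6b (0.27), Cdkn1a (0.0516) and Mcl1 (0.0438). Hmox1 was at 0.28 with library totals and Nos2 at -0.36 with the strongest region. With background scaling they were Nos2 (-1.03), Arg1 (-0.0270), Mrc1 (-0.44), Il10 (-0.73), Col5a1 (-0.0386) and Prrx1 (-0.0413). Among lists called in either setting, as signed -log10 adjusted p, hypoxia and glycolysis (0.212) and cell cycle (0.027) changed direction with cyclic loess and the wound list (-1.43) with fry. Apart from the shift built into background scaling, the cause was not tested.

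The replicate block gave 16697 regions higher and 17273 lower, 5600 genes higher and 9671 lower, and 15 lists, with fibroblast markers no longer called (adjusted p = 0.0708) and classical inflammatory activation (0.00940) and NRF2 targets (0.00770) called in addition. Across regions, deviations from the group mean correlated at 0.0163 between libraries with the same number. Both numbers give the same value by construction, since each group has 2 libraries. The labels do not say that numbers pair cultures. The DESeq2 and edgeR count tests were not run because the deposited values are log2. Promoter shares, promoter peaks of the lists, and GC or length corrections, with or without the block, were not run because no GRCm39 annotation was used. Pseudocounts, background scaling, width, thinning, the strongest region and regions as units were chosen after seeing the data.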

Other observations

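The genes named in this paragraph were chosen after their values were seen. Within the alternative activation list, Ccl22 rose by 1.03, Folr2 by 0.77 and Il1rn by 0.54, while Klf4 fell by 1.03. Among wound growth factor genes, Ereg, which encodes an epidermal growth factor family ligand, rose by 1.64, Hgf by 0.82 and Plaur by 0.74, while 11 genes of that list were lower, among them Vegfa (-0.83) and Sema3a (-0.57). Acod1, which encodes the itaconate-producing enzyme, rose by 1.53. Among NRF2 targets Prdx1 and Txnrd1 rose by 1.07 and 1.06 and Gpx1 fell by 1.13. Among metal handling genes, of which 4 were called higher and 12 lower, Slc31a2, Slc11a1 and Slc40a1 rose by 0.70, 0.70 and 0.52, and Cox17 fell by 0.82. All these changes are relative to the deposited scaling. On the background scale the median gene change was -1.06. With the level trend removed Klf4 was at -0.61, Gpx1 at -0.59, Cox17 at -0.52 and Vegfa at -0.38. A region nearest Cat, the catalase gene, on chromosome 2 from 103334945 to 103336721 rose by 3.47 ± 0.18, and a region nearest Cdkn2a on chromosome 4 from 89173073 to 89173373 rose by 3.09 ± 0.25 (limma SE). On chromosome 17 the windows from 80 to 85 and from 85 to 90 Mb had medians of -0.29 and -0.32 with the level trend removed, the latter the lowest autosomal window. The 4 libraries allow too few splits into pairs for a share under 0.05: limma called 33169 regions and 14677 genes in the real split and at most 0 in the others. Each of those puts a Gel and a CuNZ@Gel library in both arms, so their 0 calls are no measure of chance.

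The tests of regions called in either direction and of the X-linked shift against level were chosen after the result was seen. For the other tests the prediction was written before that test's own result was seen. The patterns themselves came from these data, and thinning was added after the data were seen. The first pattern is the fall of strong and rise of weak regions. With all libraries thinned to equal reads the gap between the strongest and weakest deciles was -0.98, compared with -0.96 before. This argues only against counting noise from unequal numbers of reads in regions. Thinning kept the regions, the scaling factors and each region's expected RPM, so it cannot decide on other effects of depth. More background reads in the CuNZ@Gel libraries could account for the pattern. Region reads per background pileup (in 1e6 reads) were 18.8 and 18.6 in Gel against 6.37 and 8.53 in CuNZ@Gel replicates 1 and 2. Within CuNZ@Gel, replicate 1 had the fewer and also the larger gap, by -0.1, although this rests on 2 libraries. Level alone leaves calls unexplained, because 61.9% of called regions were called in the same direction with the trend removed. A change in the cells themselves was not tested and stays open.

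The second pattern is the lower accessibility of X-linked regions. Removing the trend with level left X-linked regions at -0.28 relative to autosomal ones, which argues against level alone, and both CuNZ@Gel libraries showed it (-0.30 and -0.28 against the Gel mean). A different share of X copies in the cultures may account for it, and cannot be told apart from other causes: 20 of 21 X windows lay below the autosomal median. The exception, from 15 to 20 Mb, held 32 regions and had a median of -0.02.

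The third pattern is the lower accessibility near signal-induced transcription factor and stress response genes. Of 10000 level-matched lists, 0% had a median as low as that of the signal-induced list and 0.27% as low as that of the unfolded protein and integrated stress response, which argues against level alone. The housekeeping control, however, stood at 0.01%, so the test does not separate these lists from a control of widely used genes. Something that genes with strong regions share, beyond the level matched here, may account for part of it. With the trend removed the housekeeping list had camera adjusted p = 0.0977, against 1.89e-06 and 0.00909 for the other lists, and their differences from it were not tested. With an estimated correlation these became 0.753, 0.649 and 0.756, none called, but that test has too few degrees of freedom here to decide.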
